A study of Mus musculus with 6144 samples.

How the data were processed

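The series measured alternative splicing and RNA abundance of 50 mouse genes under 1536 treatments, most of them transfections of small interfering RNA (siRNA), in CGR8 embryonic stem cells and in N2A neuroblastoma cells, each in 2 replicates, 6144 libraries in all. Per the labels' protocols, cells in 96-well plates were transfected with pools of siRNAs at 50 nM, RNA was purified 48 hours later, and the 50 gene regions were amplified together by multiplex reverse transcription PCR. A later PCR added a pair of barcodes that identify the treatment, and the products were pooled and sequenced (SPAR-Seq). The files used here place the treatments on 16 plates of 96 wells. Every plate held wells with a non-targeting pool (siNT), mock-transfected wells and wells with siRNA against Mbnl genes (siMbnl), and the last plate held untreated wells as well. Of the treatments, 1416 were knockdowns of 1 named target each.

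The deposited table of counts holds, per the labels, the raw number of reads assigned to each gene region in each library, and the reads over the upstream junctions were used as the depth of a library and of an event. Another 6144 columns with reads over the downstream junctions were not used, and of these only the library totals were set beside the upstream ones. The deposited percent values are raw percent spliced in (PSI) per event and library, for which the series' design text names a table of junction combinations. The authors also deposited a score per knockdown and event, the strictly standardized mean difference, whose reference the labels do not state. A further deposited table gives, per the file headers, the authors' log2 RPM and log2 fold changes of the mock and siMbnl wells for each gene, and their p-values adjusted as a false discovery rate, with the reference of the fold changes not given in the sources used here. The submitters' processing notes name CASAVA 1.8, Bowtie, TopHat and edgeR and the mouse builds NCBIM37 and mm9, without saying which step used which. The tables used here name events by gene and, where a gene has several, by a suffix (A1 to A3), with no coordinates, so that exon positions are not given. The gene that the count and junction tables call Tcf3 is called Tcf7l1 in the PSI and expression tables and is named Tcf7l1 here, while the siRNA target Tcf3 is another gene with its own identifier.

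From these values 58 splicing events were analysed, and 6 entries that measure expression only were left out. A PSI value entered where its gene region had at least 20 upstream reads in that library. All analyses were run in R 4.3.3 with version 1.17.8 of data.table. Groups of control wells were compared by limma 3.58.1 on PSI in percentage points, with Benjamini-Hochberg adjustment over the events. An event was called at an adjusted p under 0.05 and a difference of at least 10 percentage points. For the screen, PSI was first centred on the median of the knockdowns of its plate. Each knockdown was then compared with all siNT libraries of its line, with 1 spread per event estimated over all treatments and moderated with limma, and Benjamini-Hochberg adjustment over all knockdowns and events of a line. A knockdown has 2 libraries, so its test rests on that pooled spread and assumes that every knockdown varies like the others. The difference between the lines was tested as the difference of both effects with their combined error, by the same thresholds. The test of the siMbnl effect between the lines was added after the data were seen.

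RNA abundance was tested on the counts with edgeR 4.0.16 (TMM scaling, its low count filter and the quasi-likelihood test). DESeq2 1.42.0 was the other tool. A gene was called at an adjusted p under 0.05 and a log2 fold change of at least 1 in size. For the expression screen each knockdown was compared with the siNT libraries of its line, with Benjamini-Hochberg adjustment over all knockdowns and genes of a line. All reads come from 50 amplified regions, so an abundance is relative to the rest of this panel and not to all RNA of the cell. PSI comes from the same regions, so a change in abundance was not separated from a change in the spliced product. Reads were amplified in 2 rounds of PCR without molecular identifiers, so intervals and counting limits cover counting error only.

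The median library had 70592 upstream reads in CGR8 and 70208 in N2A, and the median event had 242 reads per library in CGR8 and 403.5 in N2A. In CGR8 7 libraries and in N2A 4 libraries had under 10000 reads. They stayed in the main results, and each result except the target lists was also computed without them, which was decided after the data were seen. No library had the same counts as another. The labels call the libraries of a treatment replicates without saying whether they came from separate transfections, so p-values measure the spread between these libraries, part of which may be technical.

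Fixed before the data were examined were the groups, the tests, the thresholds, 31 lists of siRNA targets that share a complex or function, 5 lists of marker genes, and the rule for the names in the text. The rule took up to 10 events or genes with the largest change in each direction for a comparison of control wells. For the screen it took, in each line, the 12 targets with the most called events, the 6 events called in the most knockdowns with the 2 largest knockdowns in each direction, 6 pairs of target and event in each direction for the difference between the lines, 12 targets chosen in advance, the targets that are themselves measured, 6 targets and 6 genes of the expression screen, and up to 4 members of each called list. A target list was tested by a 2-sided permutation test with 100000 draws of the mean number of called events per target, with Benjamini-Hochberg adjustment over all lists and both lines. Lists overlap in some members.

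The comparisons of siMbnl with siNT wells and of knockdowns with siNT wells were checked on simulated values with known changes. Simulated PSI was drawn around the siNT means with the siNT spread for every library and the real missing values. Simulated counts used the means and spreads of the siNT libraries and the real library sizes. Shallow libraries were thus simulated with the same PSI spread as the others, so their extra noise was not covered by this check. Of changes of 15 percentage points simulated in single knockdowns, 85.6% were called in CGR8 and 92.4% in N2A, and of changes of 30 points 97.8% and 100%. Of decreases of 1.5 on the log2 scale simulated in single knockdowns, 88.5% were called in CGR8 and 94% in N2A. The comparison of siMbnl with siNT wells called 20 of 20 simulated events at 15 points in either line. The tests between the lines and of the target lists were not checked this way.

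The alternatives were a minimum of 100 reads or none, a logit scale, thresholds of 5 and 15 points or of 0.58 on the log2 scale, other scalings and no low count filter for counts, DESeq2's Wald test, the replicate number or the plate as a covariate, no plate centring, other knockdowns as the reference, the spread of the siNT wells alone, the authors' score at 3 or more in size, each replicate left out in turn, the mean of a well's replicates as 1 sample, and the omission of libraries under 10000 reads. Figures were drawn with matplotlib 3.10.9.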

Results

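Percent spliced in (PSI) of 58 alternative splicing events and read counts of 50 genes were measured under 1536 treatments, most of them siRNA knockdowns, in CGR8, a mouse embryonic stem cell line, and in N2A, a mouse neuroblastoma line. Each treatment had 2 libraries in each line, 6144 in all. In each line there were 64 libraries with a non-targeting siRNA (siNT), 64 mock-transfected libraries, 64 with siRNA against Mbnl genes (siMbnl), 48 untreated libraries and 2832 libraries from knockdowns of 1 target each. The untreated wells were on the last plate only. Libraries held 21 to 149641 upstream junction reads in CGR8 and 1742 to 127727 in N2A, with 7 and 4 libraries under 10000 reads. The siNT libraries held 33096 to 117390 reads in CGR8 and 1742 to 108744 in N2A.

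Measured genes that were themselves siRNA targets had lower read counts after their own knockdown. In N2A all 11 such targets that could be tested fell, with a median log2 fold change of -2.73. Celf1 fell by 3.82 on the log2 scale (SE 0.33), Mbnl2 by 3.32 (SE 0.23), Mbnl1 by 2.97 (SE 0.55), Srrm4 by 1.85 (SE 0.19) and Rbfox2 by 1.78 (SE 0.25). Dnmt3b, Sall4 and Tcf7l1 had too few reads in N2A to be tested. In CGR8 14 of 14 targets had a log2 fold change below 0, with a median of -1.50, and 7 of them passed the thresholds of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, among them Foxm1 at -2.33 (SE 0.16), Celf1 at -2.30 (SE 0.29) and Mbnl2 at -1.81 (SE 0.28). Mbnl1 (-1.37, SE 0.45), Rbfox2 (-1.22, SE 0.29) and Srrm4 (-2.37, SE 2.28) did not pass in CGR8. After siMbnl, Mbnl2 fell by 1.98 (SE 0.07) in CGR8 and by 3.40 (SE 0.08) in N2A, and Mbnl1 fell by 1.20 (SE 0.11) and by 3.08 (SE 0.12).

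The siMbnl wells address how loss of Mbnl proteins, regulators of alternative splicing, changed the events in each line. In N2A 20 of 55 events changed, 6 to higher and 14 to lower PSI. Inclusion fell most for Dst, from 83.8% ± 4.55 (SD, n = 63) to 17% ± 6.11 (n = 64), for Numa1, from 76.3% ± 2.09 to 13.6% ± 4.18, and for Tbc1d23, from 74.6% ± 3.31 to 18% ± 4.03. Baz2b fell from 91.5% to 39.8%, Kifc3 from 81.6% to 33%, Mllt4 from 51.6% to 12.8%, Arhgef12 from 50.8% to 17.5%, Tead1.A3 from 90.5% to 63.9%, Csnk1g3 from 86.6% to 62.2% and Itga6 from 23.98% to 1.82%. Inclusion rose for Ssbp3, from 8.83% ± 3.01 to 41.4% ± 9.36, for Tead1.A2, from 44.9% to 65.3%, for Mark2, from 9.37% to 29.1%, and for Daam1, from 50.0% to 62.6%. The events of Mbnl1 and Mbnl2 themselves rose from 48.5% to 64.2% and from 28.4% to 40.8%. In CGR8 4 of 57 events changed. Tead1.A2 rose from 79.96% ± 4.09 (SD, n = 64) to 91.3% ± 4.29 (n = 63) and Ssbp3 from 16.9% ± 3.67 to 27.2% ± 4.72. Foxm1.A1 fell from 64.7% ± 3.46 to 44.8% ± 3.81 and Baz2b from 17.5% ± 2.99 to 7.51% ± 2.54. The largest adjusted p among these named events was 3.84e-17 (limma with Benjamini-Hochberg adjustment).

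**Figure D1:**
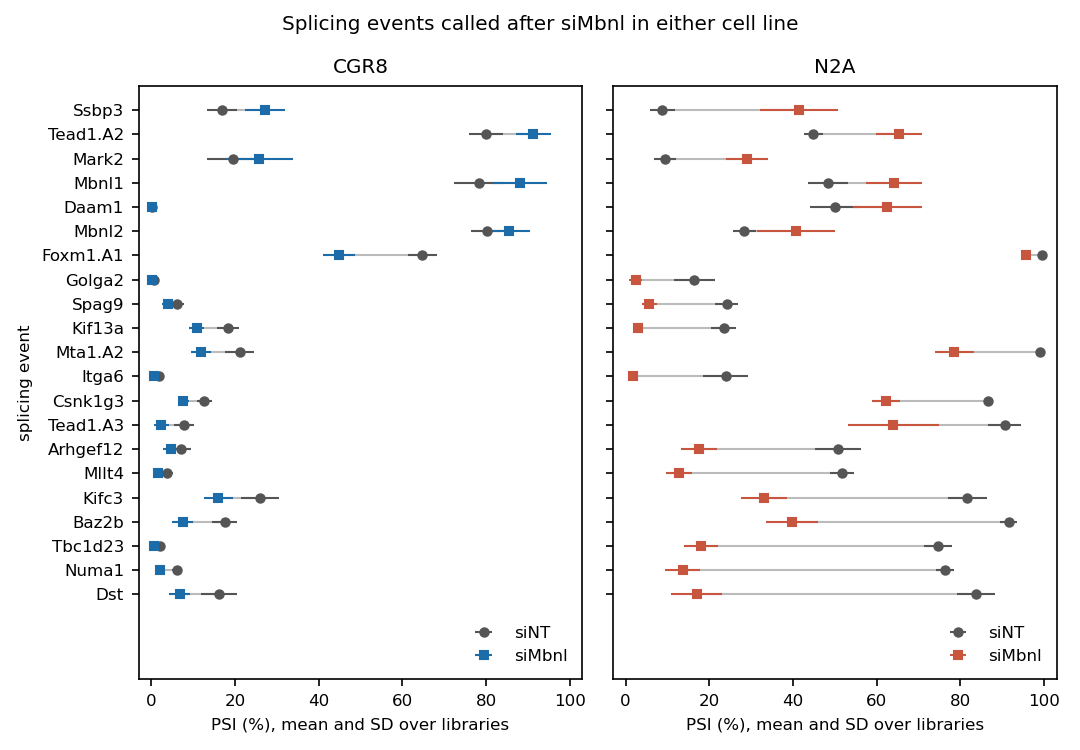
PSI in percent (horizontal axis) of each event called after siMbnl in either line, with the mean and SD over the libraries of the siNT wells (circles) and the siMbnl wells (squares). In N2A Dst, Numa1 and Tbc1d23 move from 74.6% or more to 18% or less, while in CGR8 the same events start at 16.3% or less.

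The effect of siMbnl differed between the lines for 18 of 55 events by a test of the difference itself, which was added after the data were seen. The N2A effect was lower in 14 and higher in 4. Numa1 changed by -62.6 percentage points in N2A and -4.02 in CGR8, a difference of -58.6 (SE 0.61). The differences were -57.2 for Dst, -55.1 for Tbc1d23, -41.7 for Baz2b, -38.7 for Kifc3 and -36.7 for Mllt4. The difference was 22.3 points (SE 1.44) for Ssbp3, whose change was larger in N2A, and 16.2 points (SE 0.66) for Foxm1.A1, which fell by 19.9 points in CGR8 and by 3.70 in N2A. The siNT means in CGR8 were 6.08% for Numa1, 2.04% for Tbc1d23 and 3.70% for Mllt4, and a fall there cannot exceed those values. Depletion differed as well, with Mbnl1 reads lower by 1.20 on the log2 scale in CGR8 and 3.08 in N2A, and Mbnl2 by 1.98 and 3.40. In siNT wells Mbnl1 was higher in N2A by 4.40. These limits were not separated from a difference in response between the lines.

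Transfection without siRNA left splicing near the siNT level. Between mock and siNT libraries limma called 0 events in either line, with 4 events in CGR8 and 13 in N2A at an unadjusted p under 0.05, and the largest differences were 3.39 and 2.84 percentage points. In N2A 1 event passed the adjusted p alone. Untreated and mock libraries of the last plate also gave 0 calls by limma, with 2 and 5 events at an unadjusted p under 0.05 and largest differences of 3.52 and 8.23 points, from 48 untreated and 4 mock libraries per line. In N2A 3 of these events passed the adjusted p alone.

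The lines themselves differed in baseline splicing. In siNT wells 31 of 55 events differed, with higher PSI in N2A for 22 and lower PSI for 9. Higher inclusion in N2A was found for Tead1.A3, 90.5% ± 3.95 (SD, n = 63) against 7.76% ± 2.41 (n = 64) in CGR8, for Senp6, 96.3% against 18.1%, for Mta1.A2, 98.9% against 21.1%, and for Mta1.A3, 58.0% against 0.304%. Baz2b, Csnk1g3, Tbc1d23, Numa1 and Dst were higher in N2A by 67.5 to 74 points. Arhgef11 had 59.2% ± 14.4 in the 30 N2A libraries with enough reads and 0.920% in CGR8. Lower inclusion in N2A was found for Map3k7, 6.24% ± 1.43 against 66.1% ± 5.81, for Mbnl2, 28.4% against 80.1%, for Numb, 12.6% against 48.6%, for Tead1.A2, 44.9% against 79.96%, for Nf1.A1, 7.79% against 40.0%, and for Mbnl1, 48.5% against 78.3%. Ubtf, Uspl1.A2 and Mark2 were lower by 16.6, 10.2 and 10.2 points. Each line's libraries form 1 group in the labels, so a difference between the lines cannot be separated from a difference in how they were processed.

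**Figure D2:**
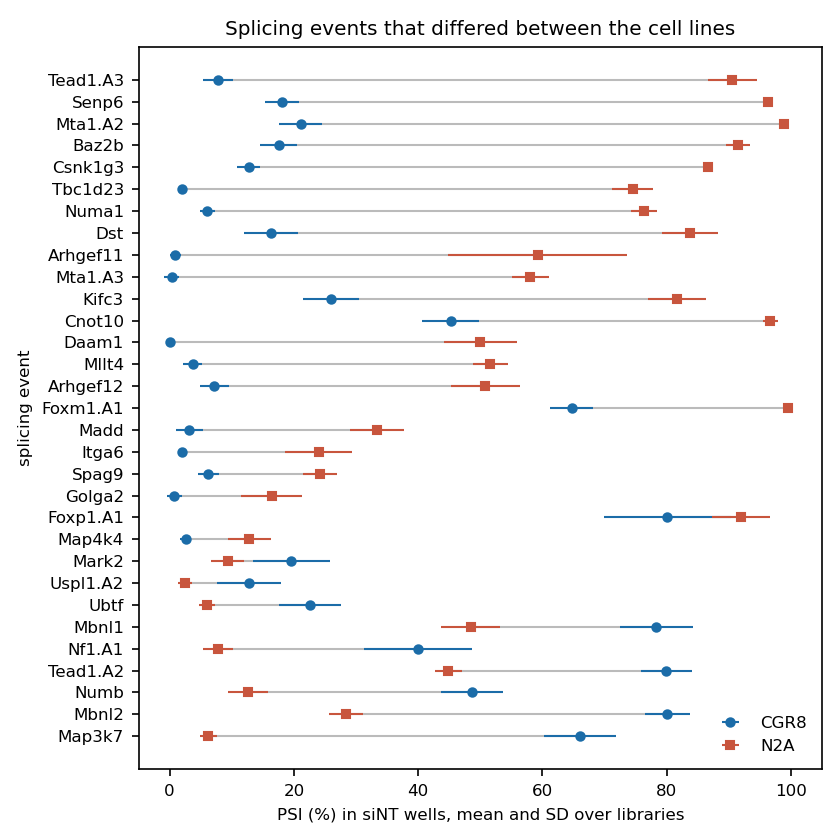
PSI in percent (horizontal axis) of the 31 events that differed between the lines in siNT wells, with the mean and SD over libraries for CGR8 (circles) and N2A (squares). Tead1.A3 shows the largest gap, from 7.76% in CGR8 to 90.5% in N2A, and Map3k7 the largest in the other direction.

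Genes typical of stem cells and of neurons separated the lines in RNA abundance. Of 49 genes tested in siNT wells 21 differed, 8 higher and 13 lower in N2A. All 3 measured pluripotency markers were lower in N2A. Sall4 had 690533 reads over the CGR8 libraries and 47 over the N2A libraries, and Fgf4 62656 and 1. In N2A 16 of the Sall4 reads were in 1 library, and those reads and the Fgf4 read came from replicate 1 on plate 15. Dnmt3b, a DNA methyltransferase, was lower at -5.04 on the log2 scale (SE 0.12). The ratio of Fgf4 shares, CGR8 to N2A, was 62475, with an exact Poisson interval at 95% from 11213 to 2.46768e+06, and rests on that 1 N2A read. The transcription factor gene Tcf7l1 had 525634 and 53 reads. Both measured neural markers were higher in N2A. Srrm4, a neuronal splicing activator, was higher by 6.44 on the log2 scale (SE 0.23), and Ptbp2, the neuronal relative of Ptbp1, by 1.47 (SE 0.05). Of the Srrm4 reads in CGR8 60.2% came from 1 library, replicate 2 of a well on plate 12, and without it the log2 fold change was 7.70 (SE 0.12). The counts adjusted over the list alone were also 3 and 2. The housekeeping gene measured, Gapdh, was lower in N2A at -1.10 (SE 0.08), but at -0.94 (SE 0.08) with DESeq2's size factors and -0.37 (SE 0.10) with library size only it was under the threshold. Of the germ layer and fibroblast markers 0 were measured.

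Other genes also differed between the lines. Mbnl1 was higher in N2A by 4.40 (SE 0.12), Srpk2 by 2.15, Madd by 1.46, Mark2 by 1.30, Slain2 by 1.28 and Mef2a by 1.27. Lower values were found for Arhgef11 (-3.28), Atg13 (-2.13), Tbc1d23 (-1.96), Daam1 (-1.53), Numa1 (-1.40) and Dst (-1.13). The scaling mattered here. With DESeq2's size factors 10 genes were higher and 9 lower, and with library size only 17 were higher and 7 lower. Scaling by library size moved the median log2 fold change of all genes from -0.14 to 0.53, and Daam1, Numa1 and Dst were then at -0.85, -0.70 and -0.48, under the threshold. Gapdh, Mllt4 and Ssbp3 also fell under the threshold with library size only, and with DESeq2's size factors these 3 and Dst (-0.98) did.

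After siMbnl few other genes passed the thresholds for abundance. By the adjusted p of edgeR alone, 16 of 48 genes in CGR8 and 33 of 45 in N2A were under 0.05. In CGR8 Mbnl1 and Mbnl2 were the 2 genes called of 48. In N2A 4 of 45 were called. Besides the Mbnl genes, Itga6, an integrin subunit, rose by 1.35 (SE 0.04) and Ssbp3 fell by 1.13 (SE 0.09). The events of both moved the other way, with PSI from 23.98% to 1.82% for Itga6 and from 8.83% to 41.4% for Ssbp3. Reads and PSI come from the same regions, so a change in abundance was not separated from a change in the spliced product. None of the measured pluripotency, neural or housekeeping markers was called after siMbnl by edgeR. In N2A Ptbp2 was at 0.30 and Srrm4 at -0.24, both with an adjusted p of at most 2.94e-08 by edgeR with Benjamini-Hochberg adjustment. Scaling by library size moved the median log2 fold change in N2A from 0.02 to -0.15. The authors' deposited log2 fold changes for siMbnl had the same sign for 2 of 2 called genes in CGR8 and 4 of 4 in N2A, and the median absolute difference over all genes was 0.05 and 0.04.

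The screen asks which factors change splicing when they are depleted. Knockdowns changed splicing far more often in N2A than in CGR8, as a count of calls. In CGR8 the siNT means of Tbc1d23, Itga6, Numa1, Mllt4 and Arhgef12, often called in N2A, were 2.04%, 1.97%, 6.08%, 3.70% and 7.16%. A fall there could not reach the threshold, and each had 0 CGR8 calls. Mbnl1 and Mbnl2, also often called in N2A, started at 78.3% and 80.1% in CGR8, with 4 and 18 calls. The median log2 fold change of a measured target after its own knockdown was -1.50 in CGR8 and -2.73 in N2A. These limits were not separated from a difference in response. In N2A 4124 of 76575 tested pairs of target and event were called, 2976 of them to lower PSI, and 890 of the targets (62.9%) had at least 1 called event. In CGR8 0.216% of 75938 pairs were called, 47 to higher PSI and the other 71.3% to lower, in 93 targets (6.57%). Control wells treated as if they were knockdowns gave 9 calls in 1689 siNT tests and 2 in 1725 mock tests in N2A, and 1 in 1731 and 0 in 1712 in CGR8. The siMbnl wells gave 620 calls in 1712 tests in N2A and 110 in 1628 in CGR8. Counted by well, 18.75% of the siNT wells and 6.25% of the mock wells had a call in N2A, and 3.125% and 0% in CGR8. Wells with a non-targeting pool or no siRNA do not show effects that other siRNAs have without their named target. In N2A the 24 targets of the germline list, where little expression was anticipated, averaged 3.08 called events against 2.91 for all other targets. Of these 24 targets 18 had a call. In CGR8 the list averaged 0.0417 against 0.117. PSI lay on the same side of the siNT mean in both libraries for 99.4% of the calls in N2A and 88.4% in CGR8. The authors' deposited score had the sign of the change for every called pair with a score, which were 99.2% of the calls in N2A and 93.9% in CGR8. Both agreements were read on pairs already called from the same libraries, so they are no separate evidence for the calls. At a size of 3 or more that score selected 60.6% of the calls in N2A and 46.3% in CGR8. With replicate 1 or 2 left out, 86.6% and 57.4% of the N2A calls and 50% and 65.2% of the CGR8 calls were made again. With the other knockdowns in place of siNT as the reference, 3021 pairs were called in N2A, 1709 of them lower, and 2348 of the 3021 were among the 4124.

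In N2A core spliceosome factors had the most called events. Knockdown of Ik, a tri-snRNP component, changed 23 events, all to lower PSI, the largest being Rbfox2 at -54.5 points (SE 1.93). The U2 snRNP genes followed, with 23 events for Sf3b2 (Senp6 -45.7), 21 for Sf3b1 (Csnk1g3 -46.8), 20 for Sf3a2 (Kifc3 -38.9) and 19 for Sf3a1 (Senp6 -52.4). Other targets were Sept2 with 21 events (Tbc1d23 -53.6), Arrdc4 with 20 (Tbc1d23 -55.2), the RNA-binding protein gene Nono with 19 (Tbc1d23 -46.4), Mbnl1 with 18 (Dst -61.9), the BTB-domain gene Nacc1 with 18 (Tbc1d23 -47.6) and Glyr1 with 18 (Numa1 -36.5). Mbnl1 reads were at -1.42 on the log2 scale after Arrdc4, -1.22 after Nacc1, -1.20 after Glyr1, -1.14 after Sept2 and -1.03 after Nono, none of them called. They were at -0.34 after Sf3a2, -0.29 after Ik and 0.09 after Sf3b1. Effects of these targets were thus not separated from lower Mbnl1. Cstf2t had 23 called events (Numa1 -42.3), but 1 of its libraries, replicate 1, held only 7665 reads. Without that library 9 events were called.

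In CGR8 the numbers were smaller. Ik had 6 called events, the largest again Rbfox2 at -39.2 points (SE 3.33), Rorc had 5 (Map3k7 -27.9) and Rbfox2 had 4 (Foxm1.A1 -26.6). Splicing factors with 4 events were Srsf3 (Ptbp2 -20.5), Sf3a3 (Numb -23.1), U2af2 (Rbfox2 -18.2), Snrnp70 (Senp6 15.9) and Sfpq (Numb 14.6), and Hnrnpu (Rbfox2 -33.8) and Srsf2 (Rbfox2 -19.4) had 3. Klf9 and Set each had 7, the most of any target, and 1 shallow library decided both. Klf9 (Mbnl2 -32.7) had 11 called events in replicate 1, with 6607 reads, and 0 without it by the limma-moderated test. Set (Map3k7 -29.6) had 15 in replicate 2, with 10303 reads, and 0 without it by the same test. The value of Srsf2 on Rbfox2 rests on replicate 1, with 30 reads for the event, and was -3.81 without it. Of the named and called pairs 44.1% in CGR8 and 26.6% in N2A no longer passed when 1 of the replicates was left out.

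**Figure D3:**
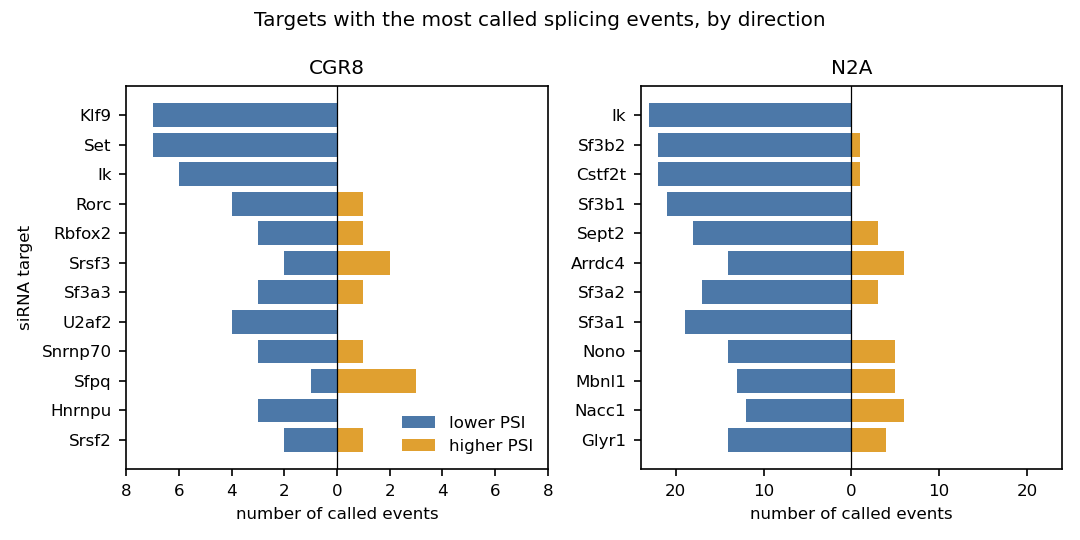
Number of called events (horizontal axis) for the 12 targets with the most in each line, split into lower PSI (left of 0) and higher PSI (right of 0). In N2A Ik, Sf3b1 and Sf3a1 have calls to lower PSI only, and in CGR8 the counts of Klf9 and Set each rest on 1 shallow library.

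Targets chosen in advance covered regulators of neuronal exons and basic spliceosome genes. In N2A knockdown of Srrm4 changed 4 events, with lower inclusion of Daam1 (-31.4 points, SE 4.24), Mta1.A3 (-16.4) and Senp6 (-11.1) and higher inclusion of Itga6 (13.3). Knockdown of Ptbp1, a repressor of many neuronal exons, changed 6, with Daam1 at 31.3 (SE 4.24), Itga6 at 22 and Madd at 16.8. Srsf11 changed 3 (Arhgef11 -30.5, Daam1 -19.7), Rnps1 changed 6 (Mta1.A3 -27.1) and the zinc finger gene Zfp871 changed 3 (Daam1 -30.8), of which Uspl1.A3 rested on replicate 2 and was at 4.79 without it. Rbfox2 changed 16, with Tbc1d23 at -53.6 (SE 3.00) and Map3k7 at 32 (SE 0.92). Mbnl3 changed 13 (Numa1 -35.3), Mbnl2 4 (Mllt4 -14.7) and Prpf8 14 (Mllt4 -36.3). In CGR8 Rbfox2 changed 4, Ptbp1 2 (Dnmt3b -11.5, Ptbp2 10.1), Sf3b1 1 (Numb -23.7) and Prpf8 1 (Mbnl2 -12.4). Without replicate 1 the values were -2.63 for Ptbp1 on Dnmt3b, 9.57 for Ptbp1 on Ptbp2 and -5.94 for Prpf8 on Mbnl2, all under the threshold. Srrm4, Mbnl1, Mbnl2, Mbnl3, Srsf11, Rnps1, Nacc1 and Zfp871 had no called event in CGR8, and their largest differences there ran from -11.0 points for Mbnl2 on Foxm1.A1 to 10.5 points for Srrm4 on Foxp1.A1.

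Some events responded to many knockdowns. In N2A Tbc1d23 changed in 31.99% of the knockdowns tested, to higher PSI in 24, with Arrdc4 and Rbfox2 the largest falls and Tcf12 (18.1) and Mysm1 (17.8) the largest rises. Itga6 changed in 25.5%, with Srsf1 at 36 and Ep400 at 23.5 against Mbnl1 at -21.3 and Celf1 at -21.1. Numa1 changed in 25.4%, to higher PSI in 2 knockdowns, with Mbnl1 at -58.7 and Arrdc4 at -53.4 against Smarca4 at 11.5 and Lsm7 at 10.7. Mllt4 changed in 23.9%, with Srsf2 at 29.2 and Srsf1 at 22.6 against Sf3a3 at -38.8 and Sf3a1 at -38.3. The Mbnl1 event changed in 23%, to lower PSI in 13 knockdowns, with Nono at 29.6 and Arrdc4 at 29 against Sf3a3 at -26.9 and Sf3a1 at -24.4. Arhgef12 changed in 21.3%, with Tcf3 at 20.8 and Mysm1 at 18.6 against Mbnl1 at -34.6 and Polr2d at -31.8. In CGR8 the numbers of knockdowns were 21 for Cnot10 (Srsf2 18.6, Dhx15 14.9, Sfswap -17.1, Prpf40a -15.9), 21 for Numb (Sfpq 14.6, Rbm19 13.8, Qk -29.1, Rbfox2 -24.8), 18 for Mbnl2 (Rorc 12.8), 16 for Map3k7 (Rbfox2 17.4, Celf1 15.2), 13 for Foxm1.A1 (Srsf3 12.7, Hnrnpk 11.9) and 10 for Ptbp2. The largest falls of Mbnl2 and Map3k7 in CGR8 were those of Klf9 and Set, and Klf9 also had the largest fall of Foxm1.A1 (-27.8).

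Knockdown of core exon junction complex genes was followed by lower PSI of the Ptbp2 event in both lines. The siNT mean was 88.9% in CGR8 and 89.2% in N2A. In CGR8 PSI changed by -40.3 points for Magoh, -37.7 for Eif4a3, -29.2 for Rbm8a and -11.7 for Casc3. In N2A it changed by -49.9, -51.9, -49.8 and -23.0. These 4 genes encode the core of the complex, which marks spliced exon junctions. Rnps1, Pnn, Magohb and Acin1, other members of the list, were not called on this event in either line, with differences from -9.11 to 6.99 points. The fall was not particular to the complex. In all, the event was called lower in 9 CGR8 knockdowns, among them Srsf3 (-20.5) and Upf1 (-12.8), and in 60 N2A knockdowns, among them Nup98 (-27.3). PSI is a share of the RNA present, so altered splicing was not separated from altered stability of a spliced form. Magoh and Eif4a3 follow from the rule for names, and the other members on this event were chosen after their values were seen.

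**Figure D4:**
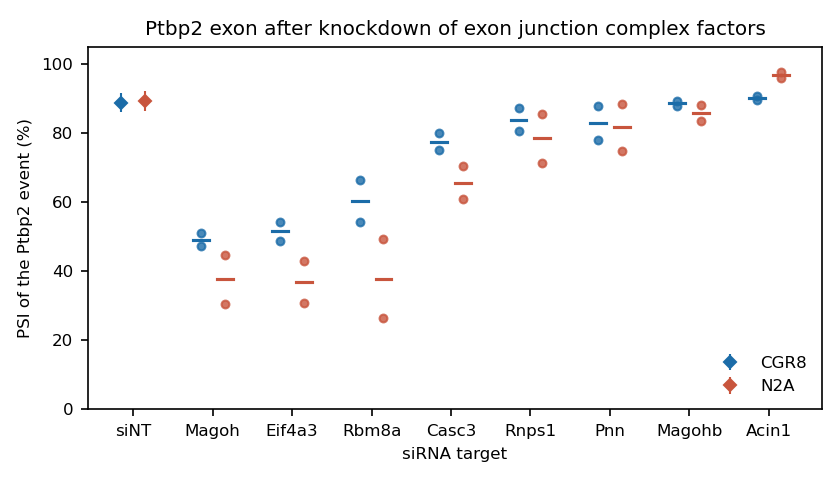
PSI of the Ptbp2 event in percent (vertical axis) for siNT wells (diamonds, mean and SD over libraries) and for knockdowns of 8 exon junction complex factors (circles are libraries, lines their means) in CGR8 and N2A. After knockdown of Magoh, Eif4a3 and Rbm8a every library lies at 66.3% or less.

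Target lists point to the U2 snRNP in both lines. Members of the list of U2 snRNP and U2AF genes had 9.73 called events on average in N2A, against 2.80 for all other targets, and 1.27 against 0.0976 in CGR8 (adjusted p 0.00031 in each, permutation test with Benjamini-Hochberg adjustment). Of the calls of the list 90.2% were to lower PSI in N2A, and 21 of 28 in CGR8. The tri-snRNP list had 5.28 against 2.87 in N2A (Ik, Eftud2, Prpf8 and Prpf38a with 13 to 23 events) and 0.56 against 0.108 in CGR8 (Ik, Snrnp200, Smu1, Eftud2), with an adjusted p of 0.0308 in each by permutation. In N2A the list of Sm and LSm core proteins had 6.83 against 2.88 (adjusted p 0.0298 by permutation), with 14 events each for Snrpd3 and Snrpd1, 13 for Snrpe and 10 for Snrpg. The N2A list of splicing regulators restricted to certain cell types had 5.45 against 2.86 (adjusted p 0.0258 by permutation), led by Mbnl1, Rbfox2, Celf6 with 14 and Mbnl3. In CGR8 U1 snRNP genes had 0.909 against 0.110 (Snrnp70 4, Prpf40a 3, Snrpc 2, Tial1 1) and microexon regulators 1.33 against 0.111 (Rbfox2 4, Qk 2, Ptbp1 2, Srsf11 0), each with an adjusted p of 0.0308 by permutation. In the U2 list of CGR8 Sf3a3 and U2af2 had 4, U2af1 3 and Sf1 2. The exon junction complex list did not pass, with an adjusted p of 0.143 in CGR8 and 0.0903 in N2A by permutation. The other lists did not pass this test either. With either replicate left out, 1 to 2 of the 4 CGR8 lists passed, and 3 of the 4 N2A lists, without the tri-snRNP list. In N2A the DNA replication list passed with fewer called events than other targets without plate centring, with a replicate block and without replicate 1, and the zinc finger list did so without plate centring.

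**Figure D5:**
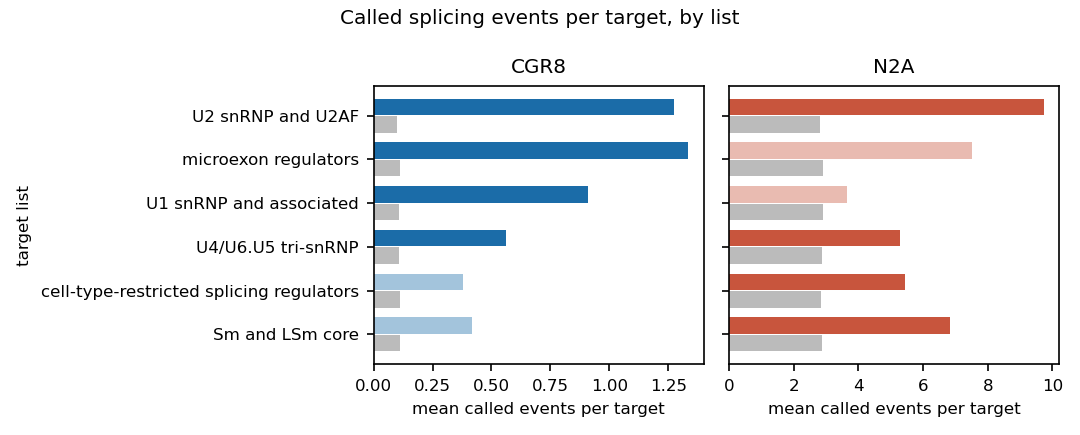
Mean number of called events per target (horizontal axis) for the 6 target lists called in either line (coloured bars, pale where the list did not pass in that line) and for all other targets (grey bars). The U2 snRNP and U2AF list reaches 9.73 events in N2A and 1.27 in CGR8.

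The difference of knockdown effects between the lines was tested for 72288 pairs of target and event, and 3497 differed, 2631 of them lower in N2A. With the other knockdowns as the reference 2516 differed, 1100 of them higher. On the logit scale 2046 differed, 1625 of them lower, and without replicate 2 the number was 2197, 1774 of them lower. Effects lower in N2A were those of Mbnl1 on Dst (-58.3 points, SE 4.79) and Numa1 (-58.0, SE 2.93), Arrdc4 on Tbc1d23 (-54.3) and Numa1 (-53.4), Sept2 on Tbc1d23 (-52.7) and Rbfox2 on Tbc1d23 (-51.8), where the siNT mean in CGR8 was 16.3% or less. Effects higher in N2A were those of Mbnl1 on Mbnl2 (38.1, SE 3.92) and Cpne1 on Daam1 (36.5, SE 4.24). Another 4 rested on 1 CGR8 library, replicate 1. For Uspl1.A3 these were Smarca5 (48.7), with PSI of 0% and 82.8% in its CGR8 libraries, Pot1a (40.8), with 0% and 95.0%, and Specc1l (36), with 0% and 87.5%. The fourth was Klf9 on Mbnl2 (39.3), with 19.7% and 71.3%. Without replicate 1 the differences were 6.11, -7.23, -17.9 and 6.91 points. Of the pairs tested in both lines 40 were called in both, 38 of them in the same direction, where independent lists would share 5.20 in the same direction. The number of called events per target correlated between the lines over all targets, with Pearson's r 0.236 and Spearman's rho 0.190 (permutation p 1e-05 for each, the smallest that the permutations can give). Without Klf9 and Set r was 0.277. Within plates r ran from -0.0881 to 0.540 and was above 0 on 14 of 16.

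In the expression screen N2A had calls in 0.578% of 63810 tests, in 16.2% of the targets, and CGR8 had 41 calls in 69386 tests, in 26 targets. The balance of directions depended on single libraries and on settings. In N2A 52.6% of the calls were higher, but 43% without the genes Sall4 and Tcf7l1, 49.2% with DESeq2's size factors, 44.7% with library size only, 43.6% with the other knockdowns of the plate as the reference, and 49.6% and 34% without replicate 1 and 2. In CGR8 31 were higher and 10 lower, but 16 and 10 without Klf9 and Set, 32 and 37 without replicate 1, and 32 and 25 without replicate 2. With replicate 1 or 2 left out, 63.4% and 49.9% of the N2A calls and 61% and 51.2% of the CGR8 calls were made again. The siNT wells treated the same way gave 1 call in N2A (0.0694% of the tests) and 1 in 1568 tests in CGR8, and the untreated wells of N2A gave 5 (0.459%). In CGR8 the siNT and the mock wells each had 1 call, or 0.0638% of the tests, against 0.0591% for the knockdowns. By well these shares were 3.125% against 1.84%. As a whole, CGR8 calls were thus no more frequent in knockdowns than in those control wells. The targets with the most called genes in N2A were Cstf2t with 13, Sf3b1 with 7 (Csnk1g3 1.64), Sf3a3 with 7 (Uspl1 1.60), Polr2a with 6 (Uspl1 -2.36), E2f6 with 5 and Polr2d with 5 (Uspl1 -2.29). Those of Cstf2t led with Daam1 at 2.29, and without its shallow library Daam1 was at -0.13. In CGR8 they were Klf9 with 8 (Baz2b 2.13), Set with 7 (Daam1 1.69), Rorc with 2 (Fgf4 -2.89), Srsf3 with 2 (Madd -1.16), Pbx3 with 1 (Srrm4 5.11) and Mapk1 with 1 (Srrm4 4.54), the last 2 each resting on replicate 2. Without the shallow libraries of Klf9 and Set, Baz2b and Daam1 were at -0.083 and -0.037.

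Among genes, Uspl1 changed in the most knockdowns of both lines. In N2A it changed in 52, with fewer reads in 46, the largest changes being -2.36 for Polr2a and -2.29 for Polr2d against 1.60 for Sf3a3 and 1.46 for Prpf8. In CGR8 it rose in 9, most after Prpf8 (1.63, SE 0.15) and Eftud2 (1.52, SE 0.15). Itga6 changed in 45 knockdowns of N2A and rose in 41, most after Prpf38a and Nono (1.68 each), and fell after Rad21 (-1.33) and Ppig (-1.27). Ptbp2 changed in 18, falling in 15 (Polr2a -1.86, Adad1 1.14), and Mbnl2 fell in 17 (Arid1a -1.66). In CGR8 Madd changed in 4, namely after Klf9 and Set, each with a shallow library, Srsf3 (-1.16) and Rest. For Rest, a repressor of neuronal genes, the change was 1.24 (SE 0.15), or 0.89 without replicate 1. Srrm4 changed in 3, after Pbx3, Mapk1 and Fam33a (4.20), but each rested on 1 library, with 0.51, -3.98 and -1.90 when that replicate was left out. Arhgef12 and Baz2b changed in 2 each, in both cases Klf9 and Set, which each have 1 shallow library. Without that library of Klf9 they were at -0.29 and -0.083. Celf1 changed in 2, at -2.27 after Rorc and at -2.30 after its own knockdown. In N2A Sall4 and Tcf7l1, near absent in siNT wells, were called higher in 32 of 43 and 30 of 45 testable knockdowns. A knockdown was testable only where the gene passed the low count filter, which favours knockdowns whose own libraries held such reads. These shares are therefore not rates over all knockdowns. In 32 of the 36 knockdowns with such a call 1 library held at least 90% of the reads.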

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

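All tests of explanations in this part were chosen after the results were seen, as was the test of the siMbnl effect between the lines, while the test of knockdown effects between the lines was planned.

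The effect of siMbnl on PSI differed between the lines, N2A minus CGR8, by -58.6 percentage points for Numa1, -57.2 for Dst, -55.1 for Tbc1d23, -41.7 for Baz2b, -38.7 for Kifc3 and -36.7 for Mllt4. Knockdown effects differed, in the same sense, for Mbnl1 on Dst (-58.3) and Numa1 (-58.0), Arrdc4 on Tbc1d23 (-54.3) and Numa1 (-53.4), Sept2 on Tbc1d23 (-52.7) and Rbfox2 on Tbc1d23 (-51.8). They differed upward for Smarca5, Pot1a and Specc1l on Uspl1.A3 (48.7, 40.8 and 36), Klf9 and Mbnl1 on Mbnl2 (39.3 and 38.1) and Cpne1 on Daam1 (36.5). The values of Smarca5, Pot1a, Specc1l and Klf9 rest on 1 CGR8 library, replicate 1, and were 6.11, -7.23, -17.9 and 6.91 without that replicate. Each was picked out because a test of the difference between the lines passed its threshold. No reported value stood out within a group of 4 libraries. Among the 4 mock libraries of the last plate, 6 of 48 events in CGR8 and 4 of 47 in N2A had a library far from the others by Dixon's criterion, which chance gives in about 1 of 20.

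Many N2A knockdowns had a splicing change that lay partly along the siMbnl change. On a score over the 20 events called after siMbnl, where siNT is about 0 and siMbnl 100, knockdown wells averaged 9.0 (SD 12.1), with Mbnl1 at 83.9, Arrdc4 at 74.1, Nono at 68, Nxf7 at 62.5, Nacc1 at 61.7 and Ube2s at 61.6, and 54.6% of the knockdowns lay above the highest siNT well. The score weighs each event by its siMbnl change, and 14 of the 20 events fell after siMbnl. A knockdown that lowers many events thus also scores high, and this was not separated from a siMbnl-like change. Sf3b1, with all 21 called events lower, scored 48.2 with Mbnl1 reads at 0.09 on the log2 scale. Ik, with all 23 lower, scored 42.1. Carry-over of siMbnl material between wells is argued against by the mock and untreated wells, whose higher mean was -1.36. Effects of siRNAs that do not need their named target may account for part of the higher scores, since targets of the germline list averaged 7.81 against 9.02 for the others. Lower Mbnl1 RNA may account for part as well: the Mbnl1 level in replicate 2 and the score in replicate 1 had r = -0.555 (rho -0.555, permutation p and its Benjamini-Hochberg value over 3 relations 1e-05, the smallest possible), -0.546 without the 2 farthest targets and -0.867 to -0.671 within the 16 plates. These explanations do not exclude each other, and effects of the named targets themselves stay open.

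Sall4 and Tcf7l1, near absent in N2A, had reads in single N2A libraries. A response to the knockdown is argued against, since in 35 of the 42 treatments with at least 20 such reads 1 library held 90% or more of them. CGR8 material in its own proportions is argued against by Fgf4, which had 70 reads (exact Poisson interval at 95% from 54.6 to 88.4) where 388.8 would be needed. Mixing of abundant CGR8 products into single libraries stays open as a candidate explanation: in 6 of 6 libraries with at least 100 such reads, PSI lay on average nearer to CGR8 than in the other replicate, by 27.4% of the distance for Mapk1, 9.0% for Hmga1, 5.57% for Hspa8, 4.41% for Dpf2, 2.07% for Grsf1 and 0.839% for Kdm5c, whose median was -0.419%. Events nearer to CGR8 were 26 of 30 for Mapk1, 23 of 31 for Hmga1, 17 of 30 for Hspa8 and for Dpf2, 18 of 31 for Grsf1 and 11 of 30 for Kdm5c. All of these libraries but that of Kdm5c are replicate 2. No other pairs of replicates were compared, so the shifts do not separate mixing from a general difference between replicates. The CGR8 library of the same Mapk1 well had 44.5% as many reads of Srrm4, a gene near absent in CGR8, as all siNT libraries of that line together, and its other replicate had 0.

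In CGR8 the targets with the most called events, Klf9 and Set, have a library with few reads. The 15 targets with a library under 20000 reads averaged 1.93 called events against 0.0964 for all others (permutation p 1e-05, the smallest possible). Klf9 and Set prompted this test, and without them the other 13 averaged 1.15 (permutation p 5e-05), so few reads in 1 library may account for many of these calls. An effect of similar size in both libraries is argued against for these targets as a set, since the deeper library moved by a median of 3.18% of the shallow one over the 29 called events, and by 17.9% over the 15 called events without Klf9 and Set. The deeper library moved the same way in 15 of the 29 and in 10 of the 15. The events were picked by the mean of both libraries, which favours large shifts in the shallow one, so a smaller shared effect stays open.

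Single libraries were regrouped at random, without keeping wells or plates together, with 100 splits counted for each comparison and the real one included. For the siMbnl, line and siMbnl expression comparisons only the real split, 1 of 100, reached its count. That is the smallest share that 100 splits can give, so chance is argued against but not excluded. The real count and the highest of the other splits were 4 and 0 for siMbnl PSI in CGR8, 20 and 8 in N2A, 31 and 20 for PSI between the lines, 2 and 0 for siMbnl expression in CGR8, 4 and 0 in N2A, and 21 and 0 for expression between the lines. For mock against siNT and untreated against mock, where limma called 0 events (4, 13, 2 and 5 at an unadjusted p under 0.05), a count of 0 is reached by 100 of 100 splits whatever the data, so the splits say nothing about chance there. The highest other was 1 for untreated wells in CGR8 and 0 in the rest.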

How the results depend on the processing

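The omission of libraries under 10000 reads and all settings of the siMbnl difference between the lines were chosen after the data were seen, and the other settings were planned. Of the alternative counts 88.3% were within 1.5 times the reported one and 21 were not. Of 3563 alternative values of named events, genes and lists 3354 kept their direction and side of the threshold, 17 came to pass, 18 reversed and the others no longer passed. The cause was not tested, except that thresholds change counts by construction. At 15 points the simulated knockdowns gave fewer calls in CGR8 (85.6% recovered) than in N2A (92.4%), and why was not tested.

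With a threshold of 5 points siMbnl changed 15 events in CGR8, untreated against mock wells 2 in N2A, and N2A knockdowns gave 7632 calls. With 15 points the counts were 1 for siMbnl in CGR8, 62 and 1736 for knockdowns in CGR8 and N2A, 1633 for the difference between the lines and 1 for CGR8 lists. A log2 threshold of 0.58 gave 10 genes for siMbnl in N2A, 33 between the lines and 1.3e+03 calls in the N2A expression screen (349.6% of the reported number). Without a read minimum siMbnl changed 7 events in CGR8. The logit scale gave 2046 differences between the lines, the share of targets with at least 3 events gave 1 CGR8 list, and other knockdowns of the plate as reference gave 54.7% of the reported expression calls in N2A (2.0e+02).

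With each replicate left out, the lone library of a knockdown being assumed to vary like the others, knockdowns gave 2.0e+02 to 250 calls in CGR8 and 2633 to 4728 in N2A, differences between the lines 2197 to 3879, CGR8 lists 1 to 2 and the CGR8 expression screen 57 to 69. All 18 reversals came from these settings. In points the ranges were -59.5 to 0.203 for Set on Map3k7 in CGR8, -44.0 to 4.79 for Zfp871 on Uspl1.A3 in N2A, and, between the lines, -7.23 to 88.2 for Pot1a and -17.9 to 90.2 for Specc1l on Uspl1.A3. On the log2 scale they were, in CGR8, -0.083 to 2.72 for Klf9 on Baz2b, -0.29 to 1.61 for Klf9 on Arhgef12, -0.037 to 2.23 for Set on Daam1, -3.98 to 4.83 for Mapk1 and -1.90 to 6.99 for Fam33a on Srrm4. In N2A they were -0.13 to 3.19 for Cstf2t on Daam1. For Sall4 they were -3.20 to 4.89 (E2f6), -3.18 to 12.24 (Mapk1), -3.19 to 9.70 (Hspa8), -3.21 to 4.23 (Rhobtb2) and -3.21 to 4.37 (Hdac10), and for Tcf7l1 -3.26 to 11.80 (Mapk1), -3.28 to 9.0 (Hmga1) and -0.072 to 3.92 (Phox2a).

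The labels do not say that a replicate number marks a shared batch, so libraries were not paired. Deviations of the same number in siNT and siMbnl wells correlated across events at 0.812 in CGR8 and 0.120 in N2A, those in siNT and mock wells at 0.787 and 0.855, and those in siNT and knockdown wells at 0.918 and 0.750. So deviations went with the number in both lines, apart from siMbnl in N2A, with 2 numbers only and events that are not independent. A replicate block gave 139.02% of the reported knockdown calls in CGR8, 4197 calls in N2A and 3861 differences between the lines, and 50 and 430 expression calls, and moved no count by over 1.5 times.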

Other observations

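No test of an explanation was run in this part, and the genes and lists in it were chosen after their values were seen.

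Reads of Uspl1, a gene of the SUMO protease family, fell after some knockdowns in N2A and rose after others. They fell in 7 of 23 knockdowns of the list of RNA polymerase II and elongation genes, all polymerase subunits, by 2.36 on the log2 scale for Polr2a, 2.29 for Polr2d, 2.15 for Polr2h, 1.90 for Polr2g, 1.78 for Polr2k, 1.65 for Polr2b and 1.51 for Polr2j. They fell in 4 of 12 knockdowns of Sm and LSm core proteins. The list of U2 snRNP and U2AF genes went both ways, with falls in 3 of 22, U2af1 (-1.81), U2af1l4 (-1.94) and Sf3b5 (-1.18), and rises in 2, Sf3a3 (1.60) and Sf3b1 (1.37). In the tri-snRNP list they rose in 3 of 25, Prpf8 (1.46), Snrnp200 (1.33) and Eftud2 (1.17). In CGR8 they rose after the same 3 knockdowns, by 1.63, 1.06 and 1.52, and in 5 of 14 knockdowns of translation factors and ribosomal proteins. Since abundances are relative to the panel, a change can also come from the other genes.

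Itga6 reads rose in N2A in 6 of 29 knockdowns of splicing regulators restricted to certain cell types and in 5 of 25 of tri-snRNP genes, and fell in 0 of either by edgeR. The targets with the highest siMbnl scores were looked at, from Mbnl1 down to Sf3b1. Itga6 was higher by 1.65 after Mbnl1, 1.51 after Arrdc4, 1.68 after Nono, 1.41 after Nxf7 and 1.22 after Ube2s. It was higher by 1.05 after Ino80e, 1.01 after Celf6 and 1.14 after Phf8. The values of 0.997 after Nacc1, 0.86 after Sf3a2, 0.46 after Sept2 and 0.03 after Sf3b1 were under the threshold. The Itga6 event is part of the siMbnl score, and the Itga6 reads come from the same region.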
